A study of Gallus gallus with 40 samples.

How the data were processed

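Liver RNA of chickens from a high growth (HG) and a low growth (LG) line was measured on a spotted cDNA array with 2 dyes. Each of the 40 arrays held HG and LG liver RNA of birds of 1 age, labelled with Alexa Fluor 555 and Alexa Fluor 647. There were 12 arrays each at 1 and 3 weeks and 4 arrays each at 5, 7, 9 and 11 weeks, and HG carried either dye on the same number of arrays within every age. Per the labels' protocols, total RNA was purified on spin columns, its integrity was checked by electrophoresis, and cDNA was labelled indirectly with the dyes. Per the series design text, replicates 5 to 12 at 1 and 3 weeks were a second round of hybridisation, in which 4 birds per line of the first round were used again beside 4 new birds. The labels do not say which arrays share birds, so arrays rather than birds entered the tests at those ages, which by itself makes the p-values there smaller. At the other ages the labels give separate birds per array.

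The deposited table holds a linear ratio of the dyes per spot and array, as its values show. The array medians of this ratio lay between 0.966 and 1.015, and the largest absolute median of its log2 was 0.04988, so the authors' values were taken as already normalized within each array, with the method not given in the sources used here. The scanner, the background correction, the filter that emptied spots and the dye in the numerator are likewise not given in the sources used here. Of 19200 spots, 7291 to 13434 had a value on an array, 4171 had a value on every array and 2892 on none. No further normalization was applied, so the number of arrays limits the precision, and ratios that the authors' normalization compressed would stay compressed.

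The log2 of each ratio was taken and spots of the same accession were averaged, which gave 18547 probes. A probe was tested where at least 75% of the arrays of every age had a value, which left 6432 probes. Gene symbols came from the platform annotation, which can be old. All 10601 annotated spots had a single symbol, the entrez ID of 10455 of them was found in the RefSeq gene table of the assembly GRCg7b, and 0 symbols needed an update. Of the probes tested, 3859 had a symbol, for 3181 genes, and 2573 had none. No genome coordinates were used.

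Differences between the lines were fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The model had a line effect for each of the 6 ages, entered as +1 or -1 by which line carried which dye, and 1 dye effect shared by all ages. All ages shared the estimate of the spread, with a median of 31 residual degrees of freedom. The contrasts were the line effect at each age, its mean over the ages, and its mean at 5 to 11 weeks minus its mean at 1 and 3 weeks (late minus early). A moderated F test asked whether the 6 effects were equal. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and the threshold was an adjusted p of 0.05. Fold changes are 2 to the power of the absolute log2 value.

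The model, the filter, the threshold, the rule for named genes, 27 gene lists and the first set of alternatives were fixed before the data were examined. The rule for named genes took, per age and for the mean, probes with a single symbol, an adjusted p under 0.05 and the same sign on at least 75% of the arrays, up to 10 per direction by size and 1 probe per gene, and for late minus early the 10 largest differences among probes past the threshold. Up to 4 members of each list with the smallest p were also eligible, and genes of growth, thyroid hormone and lipid metabolism were always looked up. Among these, IGF1, IGFBP1, DIO3, SCD, CPT1A, PIT54, CYP7A1 and THRSPA were not analysed here, since no probe for them passed the filter. The number of arrays with the same sign was counted on the turned ratio, while single array values are given after the probe's dye effect was taken off.

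The lists covered lipogenesis, cholesterol synthesis, fatty acid oxidation, lipoproteins, glycolysis, gluconeogenesis, the growth hormone, IGF and thyroid axis, haemostasis, complement, the acute phase, antigen presentation and interferon, ribosomal proteins, oxidative phosphorylation, the proteasome, chaperones of the endoplasmic reticulum, other chaperones, xenobiotic metabolism, bile acids, amino acid and urate metabolism, the cell cycle and the clock. Markers of leukocytes, erythroid cells, matrix and vessel cells, bile duct cells, neighbouring organs, and of the W chromosome with estrogen response completed the set. A gene's value was the mean of its probes, and limma's camera with a preset correlation of 0.01 compared each list of at least 5 measured genes with the other genes. This gave 25 lists and 150 tests over the ages, adjusted together. The mean and the late minus early contrast were adjusted apart. TF, TTR and ACOX2 each stood in 2 lists. Alternatives were a correlation estimated per list, fry, and a single probe per gene.

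A decision on the sign was made only after the values were seen. The rule fixed beforehand would have read the ratios as already turned to HG and LG wherever arrays of opposite orientation correlated above 0, and they did so at each age, with r across probes of 0.613 at 1 week, 0.677 at 3 weeks, 0.608 at 5 weeks, 0.232 at 7 weeks, 0.001 at 9 weeks and 0.382 at 11 weeks. The ratios were turned by orientation all the same, because 2 probes of a gene correlated in the part that changes sign with the orientation (r = 0.304 for the mean over ages, 580 genes) and less in the part both orientations share (median r = 0.0295 over 8 sets of arrays), which was therefore fitted as a dye effect. This contrast was not clear in every set, as r in the shared part reached 0.099 in replicates 1 to 4 at 1 week and 0.102 at 11 weeks, above the bounds from shuffled pairs (0.0785 and 0.0793), while r of the line effect at single ages ran from 0.109 to 0.32. Nor was the shared part the same at all ages, with r between sets of arrays from -0.154 to 0.847. Other splits of 4 arrays, in which the lines are mixed, gave r of up to 0.251 as well (9 weeks, 0.109 in the real split). Correlated probes can thus mark birds or arrays, and these r do not settle the reading. Dye effects per age and per set were fitted as alternatives chosen after the values were seen. The dye effect passed the threshold for 2531 of the 6432 probes, and counts under the other reading are given among the alternatives.

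Replicates 3 and 4 at 3 weeks have opposite orientations in the labels and nearly the same values, with r = 0.9999 over 9493 spots, an SD of their log2 difference of 0.00643 and a highest r of 0.805 for any other pair. Both were left out, since 1 sample cannot have both orientations, so 38 arrays were fitted, 10 of them at 3 weeks. Each array was also correlated with the line effect estimated from the other arrays. Replicates 1 and 2 at 3 weeks and replicate 4 at 5 weeks lay below -0.1, and the counts were repeated without them, as an alternative chosen after the values were seen. Their labels were kept.

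Further alternatives were median centring, scaling of all arrays to the same median absolute deviation (MAD), stricter and looser filters, no dye effect, a dye effect per age, array weights, the replicate number as a random block, subsets of the arrays at 1 and 3 weeks, probes averaged per gene, eBayes with trend and robust options, a separate fit per age, and leaving out each array in turn. The scripts were first tested on simulated data with 6432 probes and known changes. Of 50 probes changed 1.5-fold, 92% were called at 1 week, 98% at 3 weeks, 76% at 5 weeks, 72% at 7 weeks, 66% at 9 weeks and 64% at 11 weeks, and of 50 probes changed 2-fold, 92% were called at 5 weeks and 94% at 7, 9 and 11 weeks. Across the comparisons 7 to 17 unchanged probes were called. The simulated noise was independent between arrays, with the same spread and dye effect per probe at all ages. In the data the median residual SD ran from 0.123 at 11 weeks to 0.356 at 7 weeks. The shared part of the ratio also changed between ages, and birds were reused at 1 and 3 weeks. These shares and false calls therefore hold for the simulated setting only.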

Results

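Livers of juvenile broiler chickens from a pair of lines, selected in opposite directions for body weight, were compared at 6 ages between 1 and 11 weeks. Each array set high growth (HG) liver against low growth (LG) liver of the same age, with 12 arrays each at 1 and 3 weeks and 4 each at 5, 7, 9 and 11 weeks. The comparisons ask which liver transcripts differ between the lines at each age and whether that difference depends on age. A value was present for 7291 to 13434 spots per array. The median standard error (SE) of a log2 ratio was 0.0715 at 1 week, 0.0772 at 3 weeks, 0.121 at 5 and 7 weeks, and 0.122 at 9 and 11 weeks. These rest on a spread pooled over the ages, with a median residual SD of 0.245. From the arrays of each age alone it was 0.141 at 1 week, 0.128 at 3 weeks, 0.266 at 5 weeks, 0.356 at 7 weeks, 0.145 at 9 weeks and 0.123 at 11 weeks. The pooled p-values are therefore too small at 7 weeks and, to a lesser degree, at 5 weeks. In separate fits per age 4, 1, 0, 25, 2 and 5 probes passed at the 6 ages (limma). At 1 and 3 weeks the arrays came from 8 birds per line, some of them used more than once. That reuse makes p-values at those ages smaller, while the pooled spread, above their own, makes them larger, and the net effect was not determined.

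The sources do not state which dye is the numerator. Values are therefore log2 ratios, positive on the side of ORM1, an acute phase glycoprotein of plasma, and negative on the side of TTR, the carrier of thyroid hormone and retinol. If the ratio is 647 over 555, the likely reading because the labels call these dyes red and green, genes on the ORM1 side were higher in HG liver and genes on the TTR side in LG liver. If it is 555 over 647, the lines change places. The direction is not settled, and neither is whether the deposited ratios had already been turned to HG and LG. The values here rest on the reading that they had not. Arrays of the same orientation did not always run together, with a lowest r of -0.353. Set against the line effect of the other arrays, 31 of 38 arrays had r above 0 across probes. Replicates 1 and 2 at 3 weeks (r = -0.196 and -0.166) and replicate 4 at 5 weeks (r = -0.381) ran against their labelled orientation.

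**Figure D1:**
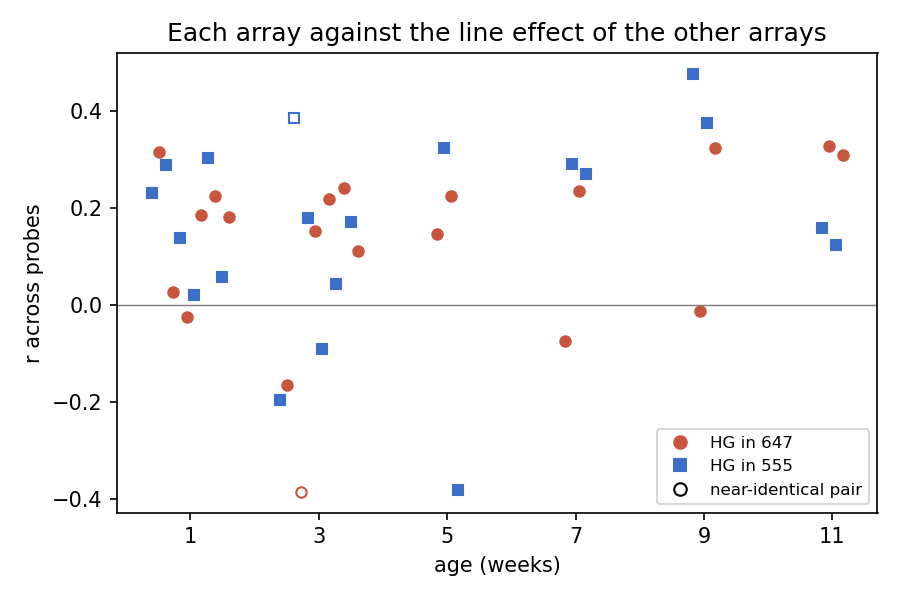
Correlation across probes of each array with the line effect estimated from the other arrays (vertical axis, r) by age in weeks (horizontal axis), with circles for HG in 647, squares for HG in 555 and open symbols for the near-identical pair at 3 weeks. Among the 38 arrays fitted r ran from -0.381 to 0.476, and 31 lay above 0.

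Lipogenic genes stood together on the TTR side at 1 week, although no single gene among them passed the threshold. FASN, the fatty acid synthase, had a mean over its probes of -0.48 (log2, SE 0.12, 1.39-fold, 12 arrays, adjusted p = 0.465). Its probes had -0.75 (12 arrays) and 0.015 (9 arrays), so the first stood alone on the arrays where the second had no value. ACLY, which makes cytosolic acetyl-CoA, had -0.47 (SE 0.17, 1.39-fold, adjusted p = 1). Of 13 lipogenesis genes 0 passed (limma) and 1 did adjusted over the list alone, and 3 were positive. Their median was -0.053, and the list shifted against the other genes (camera adjusted p = 6.67e-07, and 0.0003 with an estimated correlation). ORM1 had 0.67 (SE 0.17, 1.59-fold, adjusted p = 0.623 as a probe). A single probe passed, an unnamed clone singled out after its value was seen, at -0.98 (SE 0.16, 1.97-fold, adjusted p = 0.00296, limma), with the same sign on 9 of 9 arrays that valued it. Among 6432 probes 86 had an unadjusted p under 0.05. With all arrays scaled to the same MAD 10 probes passed, 7 on the ORM1 side and 3 on the TTR side.

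Acute phase genes shifted to the ORM1 side at 3 weeks by little, with a median of 0.016 over 10 genes (camera adjusted p = 0.00168, and 0.00397 with an estimated correlation). Without the 3 arrays that ran against their orientation the adjusted p was 0.0378, and the adjusted p was 0.239 with an estimated correlation besides. Of these genes 0 passed the threshold and 0 did adjusted over the list alone. ORM1 had the value 0.46 (SE 0.19, 1.37-fold, 10 arrays, adjusted p = 1), and TF, transferrin, had 0.11 (SE 0.066, 1.08-fold). Genes of xenobiotic metabolism had a median of 0.027 (23 genes, 0 past the threshold and 0 adjusted over the list alone, camera adjusted p = 0.0124). Its adjusted p was 0.0776 with an estimated correlation and 0.108 with scaled arrays. That shift had an unadjusted p of 0.103 without replicate 1 and an adjusted p of 0.787 without the 3 arrays that ran against their orientation. For single probes limma called 0 at 3 weeks, where 27 had an unadjusted p under 0.05. In other settings 6 passed with array weights, and 1 each with scaled arrays and in a separate fit.

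At 5 weeks the ORM1 side held GPRC5C, an orphan receptor, at 1.19 (SE 0.16, 2.28-fold, adjusted p = 1.91e-05, 4 of 4 arrays). LY6E, an interferon-inducible surface protein, stood at 1.17 (SE 0.16, 2.24-fold, adjusted p = 1.53e-05, 4 of 4 arrays), whose other probe also passed. OASL, NMI and GBP1, each inducible by interferon, had 0.83, 0.58 and 0.48, and LYG2, a lysozyme of the goose type, had 0.88. The list of antigen presentation and interferon genes did not pass, with a median of 0.091 over 12 genes, 1 of them past the threshold (OASL) and 1 adjusted over the list alone (camera adjusted p = 0.122, but 0.0431 with a single probe per gene). The TTR side held TTR itself at -1.25 (SE 0.27, 2.38-fold, adjusted p = 0.0112, 3 of 4 arrays) and in its other probe at -0.63. AKR1D1, a reductase of bile acid synthesis, had -0.79, ATIC, an enzyme of purine synthesis, -0.80, ATP5H, a subunit of ATP synthase, -0.67, and MBL2, a lectin of complement, -0.60. In OASL the other 2 probes, at 0.20 and 0.13, did not pass. In ATP6V1A, a proton pump subunit at -1.06, the other probe had 0.09. Ribosomal protein genes shifted to the TTR side (29 genes, median -0.065, 6 positive, 0 past the threshold, 2 adjusted over the list alone, camera adjusted p = 0.00101). Their adjusted p was 0.36 with an estimated correlation.

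In total 50 probes passed at 5 weeks, 24 on the ORM1 side and 26 on the TTR side, among 569 with an unadjusted p under 0.05 (limma, 4 arrays). Named genes past the threshold numbered 18. Of the 17 that the naming rule took, GPRC5C, LY6E, KLHDC8A, OASL and GSL also passed without each array in turn. The other 12 did not. Without replicate 2 the call of NMI (adjusted p = 0.456) and of AKR1D1 (0.503) ended, and ATIC missed the threshold without replicate 1 or 2 (up to 0.456). The others, among them TTR (up to 0.333), ATP5H (0.239), MBL2 (0.262), LYG2 (0.623) and GBP1 (0.562), missed it without replicate 1, 2 or 3. Without replicate 4 the count was 946, 617 and 329 on the sides of ORM1 and TTR. It was 14 without replicate 1, 16 without replicate 2 and 26 without replicate 3. Scaling to the same MAD left 2 probes, both on the ORM1 side.

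At 7 weeks the acute phase list shifted to the ORM1 side and 4 of 8 metabolic lists to the TTR side (camera), while single enzymes were called on both sides. Of these 4 lists, xenobiotic metabolism alone also passed with an estimated correlation. ORM1 reached 2.19 (SE 0.30, 4.57-fold, adjusted p = 7.97e-06). CP, the copper carrier ceruloplasmin, had 1.54 (SE 0.20, 2.91-fold, adjusted p = 3.54e-06), and TF 0.93 (SE 0.10, 1.9-fold, adjusted p = 5.22e-07 as a gene), each over 4 arrays. The fibrinogen chains FGB and FGA, which form clots, had 1.35 (2.55-fold) and 1.25 (2.38-fold). HSPA5, the main chaperone of the endoplasmic reticulum, had 1.62 (SE 0.30, 3.07-fold, adjusted p = 0.000798). CREB3L4, a transcription factor anchored in that membrane, had 1.54 (2.92-fold), and VNN2, a pantetheinase, 2.02 (4.05-fold, adjusted p = 2.07e-06). HSD11B1B, an enzyme of glucocorticoid metabolism, had 1.42 (2.68-fold, adjusted p = 0.00332). On the TTR side GATM, which makes the precursor of creatine, had -2.69 (SE 0.36, 6.46-fold, adjusted p = 6.49e-06), and SULT, a sulfotransferase, -2.32 (SE 0.33, 4.99-fold, adjusted p = 1.63e-05). THRSP, a lipogenic protein induced by thyroid hormone, had -2.23 (SE 0.40, 4.69-fold, adjusted p = 0.000525), and LBFABP, the basic fatty acid binding protein of liver, -2.02 (SE 0.25, 4.04-fold, adjusted p = 1.1e-06). TTR had -1.63 (SE 0.27, 3.1-fold) and -1.06 (SE 0.16, 2.08-fold) in its probes. FASN had -1.65 (3.13-fold, adjusted p = 0.00806) in a probe whose partner had 0.14. EZH2, the methylase of histone H3, had -2.22 (4.65-fold) with a second probe at -0.04, and ATP6V1A -1.60 with a second probe at 0.07.

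All 20 genes that the rule named at 7 weeks had the same sign on 4 of 4 arrays except EXOG (1.64, 3 of 4). Of them 17 passed without each array in turn. EXOG missed the threshold without replicate 3 or 4 (adjusted p up to 0.0966), FGB without replicate 1 (0.0778), and FASN without replicate 2 or 3 (up to 0.114). Altogether 187 probes passed, 84 on the ORM1 side and 103 on the TTR side, for 93 named genes, among 750 with an unadjusted p under 0.05 (limma). Without replicate 1 the count was 370, with 151 and 219 on these sides. Scaling to the same MAD left 15 probes, 5 on the ORM1 side and 10 on the TTR side. With a dye effect per age and set 435 passed, 228 and 207 on these sides.

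Of 10 acute phase genes, 3 passed on the ORM1 side at 7 weeks (ORM1, CP and TF) and 4 did adjusted over the list alone. The list had a median of 0.096 and a mean of 0.44 and shifted (camera adjusted p = 0.000828, and 0.0016 with an estimated correlation). Chaperones and stress genes of the endoplasmic reticulum moved the same way, with 13 of 15 positive, HSPA5 past the threshold and 4 adjusted over the list alone. Their median was 0.13 (camera adjusted p = 0.0106, and 0.0432 with an estimated correlation), but with a single probe per gene the adjusted p was 0.112. HBBA, a globin of red cells, moved to the same side (0.86, SE 0.12, 1.81-fold, adjusted p = 1.13e-05). The erythroid list did not pass (7 genes, median 0.14, 1 past the threshold and 1 adjusted over the list alone, camera adjusted p = 0.122). That list had an unadjusted p of 0.000122 without replicate 1 and 0.0375 without replicate 2. Leukocyte markers had a median of 0.098 (8 genes, 0 past the threshold, 0 adjusted over the list alone, adjusted p = 0.469).

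Of 8 metabolic lists 4 shifted to the TTR side at 7 weeks, and xenobiotic metabolism alone of these passed with an estimated correlation. Xenobiotic metabolism had 3 of 23 genes past the threshold, the glutathione transferase GSTA3 (-1.36, 2.56-fold), the cytochrome P450 CYP2C23a (-0.77) and the sulfotransferase SULT1C3 (-0.99), and 7 adjusted over the list alone. Its median was -0.11 (camera adjusted p = 0.00596, and 0.0432 with an estimated correlation). In amino acid and urate metabolism 3 of 22 passed, HGD (-0.81) and TAT (-0.86), which break down tyrosine, and DPYS (-1.05), which breaks down pyrimidines, and 7 did adjusted over the list alone. The median was -0.092 (camera adjusted p = 0.00339, but an adjusted p of 0.426 with an estimated correlation). Bile acid genes were 0 of 7 positive, with SLC51A, part of a bile acid exporter, at -0.73 (1.65-fold) and 1 of 7 past the threshold and adjusted over the list alone. They had a median of -0.20 (camera adjusted p = 0.00362, but an adjusted p of 0.12 with an estimated correlation). Lipogenesis had THRSP and FASN, the latter as the mean of its probes (-0.75), among 13 genes past the threshold and adjusted over the list alone (median -0.15, camera adjusted p = 0.0171). The adjusted p was 0.15 with an estimated correlation, 0.0952 with scaled arrays and 0.0894 with a single probe per gene. Ribosomal protein genes had a median of -0.069, 0 past the threshold and 3 adjusted over the list alone (29 genes, camera adjusted p = 0.0155). Their adjusted p was 0.548 with an estimated correlation and 0.072 with scaled arrays. HBBA, of red cells, lay on the other side (0.86). Unadjusted p-values of these lists rose past 0.05 without replicate 2 for lipogenesis (0.0969), ribosomal proteins (0.737), bile acids (0.0708) and amino acids (0.136). They did so without replicate 3 for xenobiotic metabolism (0.0621) and amino acids (0.0576).

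Other lists did not shift at 7 weeks by camera. They were cholesterol synthesis (adjusted p = 0.897, 0 of 13 genes past the threshold), fatty acid oxidation (0.451, with EHHADH of the peroxisome past it at 0.83), glycolysis (0.779), gluconeogenesis (0.469, with FBP1 at -0.63) and lipoproteins (0.772, with TTR). Nor did the growth hormone, IGF and thyroid axis (0.469, with TTR), haemostasis (0.495, with FGA and FGB), complement (0.711, with C8A at 0.84) or antigen presentation and interferon (0.257, with B2M at 0.77). Further unshifted lists were oxidative phosphorylation (0.098, with ATP5H at -0.93 and SDHD at 0.52), the proteasome (0.469), cytosolic and mitochondrial chaperones (0.744), the cell cycle (0.918, with TOP2A at 0.53) and the clock (0.871), as well as markers of matrix and vessel cells (0.779) and of neighbouring organs (0.744). Single arrays mattered here. Without replicate 2 haemostasis had a median of 0.412 (unadjusted p = 0.00175) and complement one of 0.0925 (unadjusted p = 0.0274), both on the ORM1 side, and antigen presentation an unadjusted p of 0.0472. Without replicate 3 haemostasis (0.0463) and antigen presentation (0.0473) were under 0.05 too, unadjusted. Without replicate 1 haemostasis had a median of -0.145 (unadjusted p = 0.351), and on the TTR side fatty acid oxidation (0.0308), lipoproteins (0.0319) and oxidative phosphorylation (0.00315) had an unadjusted p under 0.05. Oxidative phosphorylation also did without replicate 3 (0.0152) or 4 (0.0225). Adjusted over the list alone, 3 genes each passed in haemostasis, lipoproteins, antigen presentation and oxidative phosphorylation, and 1 in cholesterol synthesis. Median, mean and test differed in sign for cholesterol synthesis (median 0.004, mean 0.0042, test on the TTR side). They also did for lipoproteins (median 0.063, mean -0.016), gluconeogenesis (median 0.008, mean -0.098), the growth hormone axis (median 0.066, mean -0.12) and the cell cycle (median -0.0096, mean 0.018). Bile duct markers (3 genes, 0 past the threshold) and the genes of the W chromosome and estrogen response (2 genes, TF past it, HINTW at 0.12) were too few to test as lists.

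At 9 weeks SULT stood on the TTR side at -2.39 (SE 0.33, 5.23-fold, adjusted p = 2.56e-05) and FASN at -1.61 (SE 0.38, 3.06-fold, adjusted p = 0.026), whose other probe had -0.0081. AKR1D1 stood at -0.86 (SE 0.17, 1.81-fold, adjusted p = 0.00342) and ABHD4, a lipase of N-acyl phospholipids, at -0.71 (SE 0.11, 1.63-fold, adjusted p = 0.000166), and all 4 genes had the same sign on 4 of 4 arrays. WASF2, a regulator of actin, had -1.55 on 3 arrays (2.92-fold), while its other probes had 0.13 and -0.09 and did not pass. The ORM1 side held STK39, a kinase that acts on ion transporters, at 0.58 (SE 0.10, adjusted p = 0.00084), and CYP4B7, a cytochrome P450, at 0.41. No list shifted (lowest camera adjusted p = 0.098).

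In total 54 probes passed at 9 weeks, 8 on the ORM1 side and 46 on the TTR side, for 25 named genes, among 732 with an unadjusted p under 0.05 (limma, 4 arrays). The larger side depended on the model, with 121 and 105 on the sides of ORM1 and TTR with a dye effect per age, 194 and 135 with a dye effect per age and set, 568 and 379 with array weights, and 13 and 57 with scaled arrays. The count was 27 without replicate 1 and 23 without replicate 4. STK39, SULT, WASF2, PRDM10 and ABHD4 passed without each array in turn. The other 9 of 14 named genes did not, among them AKR1D1 without replicate 2 (adjusted p = 0.0813), FASN without replicate 1, 3 or 4 (up to 0.414) and CYP4B7 without replicate 2, 3 or 4 (up to 0.325). PRDM10 lay on the TTR side, while its other probe lay on the ORM1 side and did not pass.

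At 11 weeks MED27, a subunit of the Mediator complex, had 1.38 (SE 0.16, 2.60-fold, adjusted p = 2.45e-06), and GPT2, an alanine aminotransferase, had 1.19 (SE 0.24, 2.29-fold, adjusted p = 0.0127). TF had 0.47 (SE 0.10, 1.39-fold, adjusted p = 0.0216), and TIMP2, an inhibitor of matrix proteases, the same. On the TTR side stood SULT at -1.77 (SE 0.33, 3.41-fold, adjusted p = 0.00439) and ATIC at -0.74 (1.67-fold). ADH4, an alcohol dehydrogenase, stood at -0.56 (SE 0.090, 1.47-fold, adjusted p = 0.000412), and MCU, the calcium channel of mitochondria, at -0.53 (1.44-fold). The acute phase list shifted to the ORM1 side (10 genes, median 0.10, 1 past the threshold and 2 adjusted over the list alone, camera adjusted p = 0.0391). Its adjusted p was 0.0916 with an estimated correlation, 0.0952 with scaled arrays and 0.118 with a single probe per gene. It was 0.073 with a dye effect per age and set and 0.058 without the 3 arrays that ran against their orientation. Ribosomal protein genes had a median of -0.051 (0 past the threshold and 0 adjusted over the list alone, camera adjusted p = 0.0397). Here the adjusted p was 0.638 with an estimated correlation, 0.0502 with scaled arrays, 0.118 with a single probe per gene and 0.0533 without those arrays. The unadjusted p was 0.278 for the acute phase without replicate 4 and 0.35 for ribosomal proteins without replicate 3.

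In total 25 probes passed at 11 weeks, 12 and 13 on the sides of ORM1 and TTR, for 15 named genes, among 268 with an unadjusted p under 0.05 (limma, 4 arrays). The count was 14 without replicate 2 and 11 without replicate 4. MED27, ADH4, MCU and MBD2 passed without each array in turn, whereas SULT missed the threshold without replicate 4 (adjusted p = 0.338) and GPT2 without replicate 1, 2 or 3 (up to 0.233). So did TF without replicate 1, 3 or 4 (up to 0.561), TIMP2 without replicate 1 or 4 (up to 0.523) and ATIC without any of the 4 (up to 0.335). The other probe of MBD2 lay on the ORM1 side and did not pass. ADH4 also had another probe, on the TTR side, that did not pass.

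**Figure D2:**
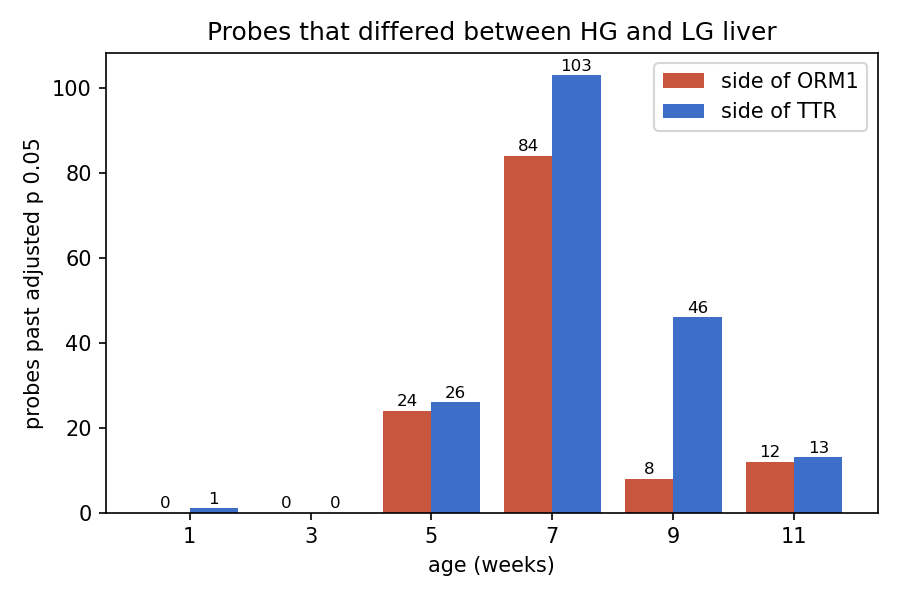
Number of probes past an adjusted p of 0.05 (vertical axis, limma, of 6432 tested) by age in weeks (horizontal axis), with bars for the side of ORM1 and the side of TTR; which line is the higher on each side depends on the unstated direction of the ratio. The counts were 1, 0, 50, 187, 54 and 25 at 1, 3, 5, 7, 9 and 11 weeks.

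Probes called at one age were often called at another with the same sign. At 7 and 9 weeks 20 were shared, all 20 with the same direction, where independent lists would share 1.57 and independent lists within 10 bins of the pooled spread 2.1, among them SULT, FASN, STK39 and WASF2. At 9 and 11 weeks 8 were shared (0.21 and 0.281 in such lists), among them SULT and MCU. There were 8 at 7 and 11 weeks (0.727 and 1.09), among them ADH4, MED27, TF and SULT. At 5 and 7 weeks there were 10 (1.45 and 2.31), 9 with the same direction, among them TTR, ATP5H and ATP6V1A. ATIC was the named gene among the 2 shared by 5 and 11 weeks (0.194 and 0.231), and AKR1D1 the gene shared by 5 and 9 weeks (0.42 and 0.46). All ages came from 1 fit with a single spread per probe, so a probe with a small spread is called more easily at several ages, which the bins allow for only in part. Probes of the same transcript and co-regulated genes are not independent either, so no test of the overlap is given.

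**Figure D3:**
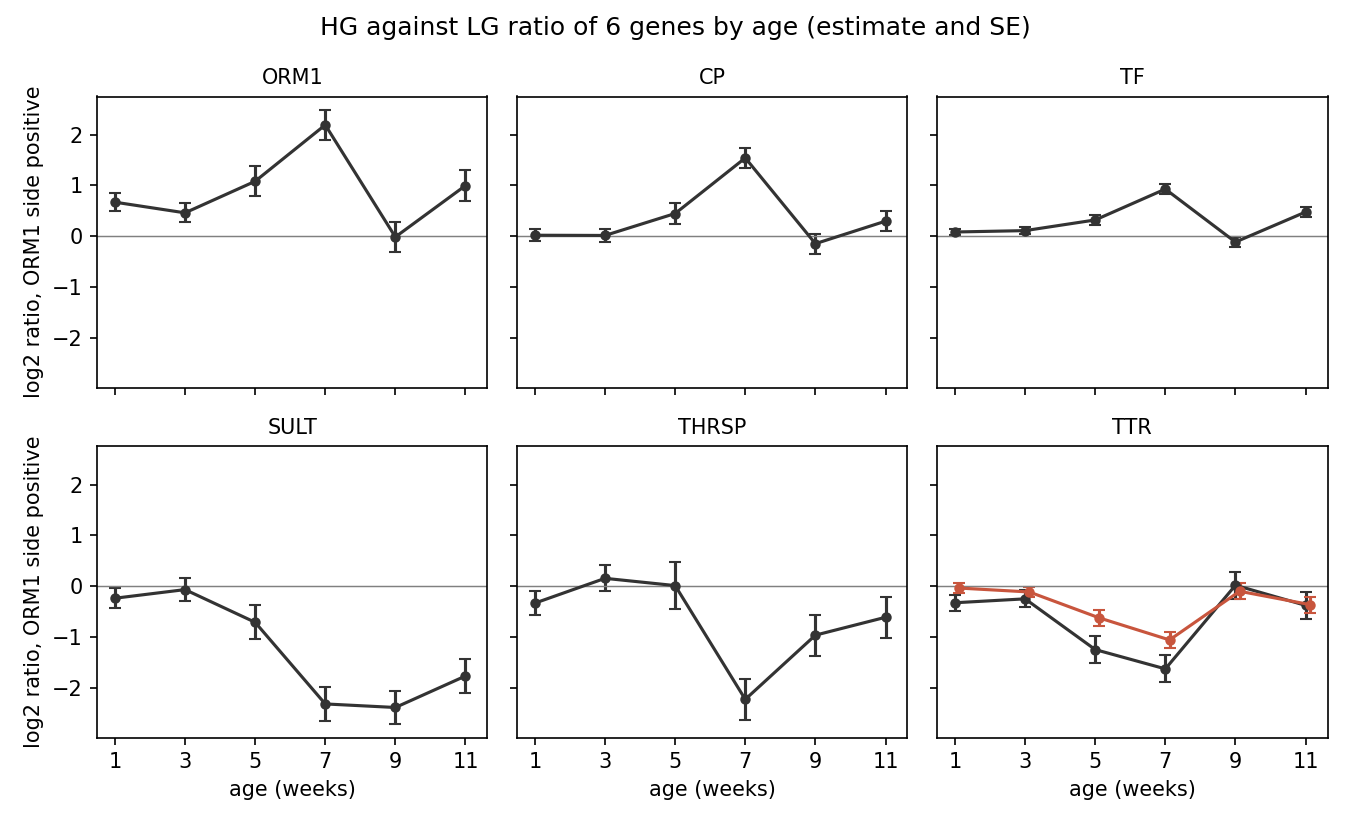
Log2 ratio between the lines (vertical axis, ORM1 side positive, points are limma estimates and bars their SE) of 6 genes by age in weeks (horizontal axis); TTR has 2 probes, in different colours, and which line is the higher depends on the unstated direction of the ratio. ORM1 peaked at 2.19 and THRSP reached -2.23 at 7 weeks, while SULT had -2.32, -2.39 and -1.77 at 7, 9 and 11 weeks.

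Averaged over the 6 ages, SULT had -1.25 (SE 0.12, 2.38-fold, adjusted p = 9.3e-09, same sign on 31 of 37 arrays) and FASN -0.87 (SE 0.14, 1.83-fold, adjusted p = 4.72e-05, 32 of 38). The other probe of FASN had 0.027 (adjusted p = 0.666), and their mean as a gene was -0.44 (SE 0.074, adjusted p = 8.5e-05). GATM had -0.81 (SE 0.13, 1.75-fold, adjusted p = 6.92e-05) and ATP5H -0.44 (SE 0.051, 1.36-fold, adjusted p = 2.08e-07, 32 of 38). The ORM1 side held ORM1 at 0.90 (SE 0.11, 1.86-fold, adjusted p = 4.68e-07, 30 of 38 arrays) and MED27 at 0.56 (1.47-fold). AGT, the precursor of angiotensin, had 0.36 (1.28-fold, adjusted p = 0.00264) and C8A of complement 0.32 (adjusted p = 0.00346). In all 277 probes passed, 84 and 193 on the sides of ORM1 and TTR, for 139 named genes, among 953 with an unadjusted p under 0.05. Of the named genes called, 15 of 18 passed without each array in turn. LOC422154 missed the threshold without any 1 of 27 arrays (adjusted p up to 0.114), TM4SF1a without replicate 2 at 7 weeks (0.0501) and LOC428335 without replicate 2 or 3 at 5 weeks or 2 at 7 weeks (up to 0.0655). Without the 3 arrays that ran against their orientation and with a dye effect per age and set the larger side turned, with 975 and 632 on the sides of ORM1 and TTR. The count was 633 without replicate 4 at 5 weeks and 518 without replicate 1 at 7 weeks.

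Over the mean, the acute phase list lay on the ORM1 side, with 4 of 10 genes past the threshold and 5 adjusted over the list alone. CEBPB, a transcription factor of that response, was the 1 of these 4 on the TTR side (-0.15). The camera adjusted p was 0.00588, and 0.0264 with an estimated correlation, but 0.171 without the 3 arrays that ran against their orientation. Ribosomal proteins lay on the TTR side with RPS10, RPS20, RPS6, RPL23 and RPL5 past the threshold, 5 of 29, and 7 adjusted over the list alone. Their camera adjusted p was 0.000253, but the adjusted p was 0.128 with an estimated correlation. Bile acid genes had AKR1D1 (-0.45, adjusted p = 3e-06) as 1 of 7 past it and 1 adjusted over the list alone (adjusted p = 0.00179, but 0.0796 as the adjusted p with an estimated correlation). Amino acid and urate metabolism had 4 genes on the TTR side, among them ATIC (-0.43) and DPYS (-0.40), and GPT2 (0.36) on the other. Adjusted over the list alone there were 5 (adjusted p = 0.0125, but an adjusted p of 0.377 with an estimated correlation). Xenobiotic metabolism had GSTA3 (-0.39) past the threshold, 1 adjusted over the list alone and an adjusted p of 0.0314. That became an adjusted p of 0.126 with an estimated correlation, 0.0611 with scaled and 0.06 with centred arrays, and 0.0622 with a single probe per gene. Lipogenesis had FASN, THRSP and ACLY past it, 3 of 13 genes, and 3 adjusted over the list alone (adjusted p = 0.0228). The adjusted p was 0.126 with an estimated correlation, 0.0611 with scaled arrays and 0.0622 with a single probe per gene. This list lay on the TTR side by its mean of -0.11 and its test, while its median was 0.0012, which centring turned to -0.014.

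The difference between the lines itself changed with age for SULT, whose mean over 5 to 11 weeks was -1.80 against -0.15 at 1 and 3 weeks (difference -1.64, SE 0.22, adjusted p = 7.82e-05). It did so for 1 probe of WASF2 (-0.88 against -0.078, difference -0.81, SE 0.12, adjusted p = 0.000459) and for AKR1D1 (-0.67 against -0.025, difference -0.64, SE 0.11, adjusted p = 0.00119). VNN2 went the other way, with 0.94 against 0.13 (difference 0.81, SE 0.17, adjusted p = 0.00718). So did FABP1, a fatty acid binding protein of liver, with 0.66 against -0.073 (difference 0.73, SE 0.17, adjusted p = 0.0208). In all 74 probes passed, 26 and 48 on the sides of ORM1 and TTR, among 552 with an unadjusted p under 0.05. With arrays scaled to the same MAD 10 probes passed, 4 and 6 on these sides, and limma called 0 with only replicates 1 to 4, 5 to 8 or 9 to 12 at 1 and 3 weeks, where fewer arrays were fitted. The 10 genes named each passed without every array in turn. Among them EZH2, PWP2, TM2D3, CZH18ORF25 and SLC25A6 followed nearly the same course over the ages, so the 10 may not be separate signals. Of the lists, bile acid genes moved to the TTR side with age (1 of 7 past the threshold and 1 adjusted over the list alone, median -0.10, camera adjusted p = 8.66e-05, and 0.0314 with an estimated correlation). So did ribosomal proteins (0 past it, 0 adjusted over the list alone, adjusted p = 8.66e-05, 0.17 as the adjusted p with an estimated correlation) and xenobiotic metabolism (0 and 2, adjusted p = 0.012, 0.0817 as the adjusted p with an estimated correlation and 0.0624 with scaled arrays). The same held for amino acid and urate metabolism (1 and 4, adjusted p = 0.0109, 0.381 as the adjusted p with an estimated correlation and 0.15 with scaled arrays) and oxidative phosphorylation (1 and 1, adjusted p = 0.0388, 0.121 as the adjusted p with an estimated correlation, 0.0624 with scaled and 0.0539 with centred arrays, and 0.0668 without the 3 arrays above). The F test over the 6 ages called 99 probes, for 55 named genes, among 451 with an unadjusted p under 0.05. They included SULT (adjusted p = 0.000121), WASF2 (0.000153) and VNN2 (0.000661). The F test called 24 probes with scaled arrays, and 0, 7 and 7 (limma) with only replicates 1 to 4, 5 to 8 and 9 to 12 at 1 and 3 weeks. Leaving out replicate 4 at 5 weeks gave 198 late minus early calls and 266 by the F test, and leaving out replicate 1 at 7 weeks gave 118 late minus early calls.

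Several genes of growth and of energy metabolism did not differ detectably at any age with these numbers of arrays (limma). GHR, the growth hormone receptor, stayed between -0.09 and 0.19. IGFBP2, which binds IGF in plasma, had its highest value at 9 weeks (0.15, adjusted p = 0.481). DIO1, which converts thyroid hormone, stayed between -0.0052 and 0.08, and PCK1, of gluconeogenesis, had 0.35 at 9 weeks (adjusted p = 0.446). APOA1, the main protein of high density lipoprotein, had -0.65 and -0.89 in its probes at 9 weeks (adjusted p = 0.26 and 0.241). THRSP and FASN passed at the ages above. Outside them THRSP had -0.97 at 9 weeks (adjusted p = 0.37) and FASN -0.75 at 1 week (adjusted p = 0.928, same sign on 11 of 12 arrays).

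The 13 list shifts at single ages kept their side under median centring and under scaling to the same MAD, and 5 of the 13 adjusted p-values were under 0.05 with an estimated correlation. By fry, 1 list passed, the chaperones of the endoplasmic reticulum at 7 weeks (adjusted p = 0.00526). Here fry asked whether the genes of a list moved in 1 direction, without comparing them with other genes. It covered the 2228 genes with a value on all fitted arrays. The other list shifts at single ages given above did not pass by fry.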

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

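The tests of the 3 patterns weighed here and the splits of 5 to 11 weeks alone were chosen after the results were seen, while the other counts over splits of the arrays were planned.

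The difference between the lines was not the same at all ages for several genes, and this was tested directly as late minus early, the mean at 5 to 11 weeks minus the mean at 1 and 3 weeks (ORM1 side positive, and which line is the higher depends on the unstated direction of the ratio). SULT, a sulfotransferase, had a difference of -1.64 (log2, SE 0.22, adjusted p = 7.82e-05, limma), EZH2 -1.09 (SE 0.22, adjusted p = 0.00656), PWP2 -0.81 (adjusted p = 0.0168), WASF2 -0.81 (adjusted p = 0.000459), TM2D3 -0.80 (adjusted p = 0.015), CZH18ORF25 -0.77 (adjusted p = 0.00575), SLC25A6, a carrier of ADP and ATP in mitochondria, -0.65 (adjusted p = 0.0116) and AKR1D1, of bile acid synthesis, -0.64 (adjusted p = 0.00119). VNN2 (0.81, adjusted p = 0.00718) and FABP1 (0.73, adjusted p = 0.0208) went to the ORM1 side. Only 1 probe each of EZH2 and WASF2 moved, since the other probe of EZH2 stayed between -0.22 and 0.08 at all ages and the other 2 of WASF2 between -0.13 and 0.13. SLC25A6 also had a second probe, with the same sign, that did not pass. EZH2, PWP2, TM2D3, CZH18ORF25 and SLC25A6 followed nearly the same course. They had -2.22, -1.67, -1.58, -1.49 and -1.26 at 7 weeks, and -0.81, -0.755, -0.797, -0.781 and -0.805 at 9 weeks. Whether their probes measure separate transcripts was not tested, so they may not be separate results. For THRSP (-0.86) and GATM (-0.77) the late minus early test did not pass (adjusted p = 0.172 and 0.142), while the F test over the 6 ages did (adjusted p = 0.0484 and 0.00303). Late minus early called 74 probes, and 3 of 100 splits of the arrays into orientations gave as many, the real one included. The highest other split gave 125. For the pooled model chance can thus be excluded at the level of 1 in 20 for a part of the ratio that follows the orientation. That part is a difference between the lines only if the ratios had not been turned when deposited. Since birds were reused at 1 and 3 weeks, the arrays of 5 to 11 weeks alone were also split, and then 1 of 81 splits, the real one, gave as many and the highest other gave 52. The count was 10 with scaled arrays, however, and 0 by limma with only replicates 1 to 4, 5 to 8 or 9 to 12 at 1 and 3 weeks, where fewer arrays were fitted, and arrays at 1 and 3 weeks had a smaller spread than those at 5 and 7 weeks. By the F test 99 were called, 47 of 100 splits gave as many, and the highest other gave 642, so chance was not excluded for that count.

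In 7 of 105 sets of array values, each 1 gene at 1 age with its dye effect removed, a single array stood apart from the others, where chance would give about 1 in 20. At 5 weeks GBP1, inducible by interferon, had 0.94 on replicate 2 against 0.257 to 0.358 on the others, and MBL2, a lectin of complement, had 0.0851 on replicate 4 against -0.899 to -0.773. At 7 weeks EXOG, a nuclease of mitochondria, had -0.255 on replicate 2 against 2.06 to 2.39. Both GHR (0.469, others -0.16 to 0.114) and APOA1 (0.852, others -0.49 to 0.199) stood apart on replicate 1 at 3 weeks, and PCK1 (-0.436, others -0.175 to 0.104) did on replicate 2 of that age, which are 2 of the arrays that ran against their labelled orientation. DIO1 had 0.217 on replicate 4 at 9 weeks against 0.0373 to 0.0435. GBP1, MBL2 and EXOG were called at these ages and the other 4 genes were not.

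The first pattern was a part of the ratio that arrays of both orientations share. A difference between the lines, in ratios already turned to HG and LG when deposited, stays open as a cause of it. This part correlated between the replicate sets 1 to 4 and 5 to 12 of 1 week (r = 0.35) less than between 1 and 3 weeks within replicates 5 to 12 (r = 0.847). But replicates 1 to 4 of 1 week were 4 arrays with a median MAD of 0.248, against 8 with 0.159 for replicates 5 to 12. Fewer arrays with a larger spread can by themselves lower r, so these r do not decide. A dye effect of each probe is a candidate explanation, since 2 probes of a gene hardly correlated in it (median r = 0.0295 over 8 sets of arrays, highest 0.102) and did so in the part that changes sign with the orientation (r = 0.304 for the mean, 0.109 to 0.32 at single ages, 580 genes). Other splits of 4 arrays, in which the lines are mixed, gave r of up to 0.251 as well, so this contrast does not separate the readings. A dye effect that is the same at all ages was argued against, since r of the shared part between sets of arrays was as low as -0.154 (5 with 9 weeks), while it was 0.655 for 5 with 7 weeks and 0.757 for 9 with 11 weeks. The limits of this test were set after these r were seen. A dye effect that differs between groups of arrays, or a part that follows age, stays open, and the single dye effect of the model was too simple. Whether the submitters turned some arrays and not others, with 3 arrays below -0.1, could not be settled from the values.

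The second pattern was that few probes passed at 1 and 3 weeks and more from 5 weeks on, in the fit with a spread pooled over the ages. It broke in other settings, with 10 probes at 1 week and 2 at 5 weeks on scaled arrays, and 29 at 1 week and 8 at 7 weeks with array weights. The pooled spread itself stays open as an explanation, since separate fits per age called 4, 1, 0, 25, 2 and 5, with 0 at 5 weeks against 4 at 1 week, but had a median of 2 residual degrees of freedom from 5 weeks on. A larger error at the early ages was argued against only in log2 units and with arrays as the unit. The median SE from the arrays of each age alone was 0.0414 at 1 week and 0.041 at 3 weeks, and at least 0.0618 from 5 weeks on. These SE treat the arrays as independent, while birds were reused, and compressed ratios would have a smaller SE too. An error that was larger relative to the differences between the lines stays open. Compression of the ratios on replicates 5 to 12 alone was argued against for 7 weeks only, since on replicates 1 to 4 the covariance between 2 probes of a gene was 0.00221 (95% interval 0.000536 to 0.00408) at 1 week against 0.0168 (0.00812 to 0.026) at 7 weeks. It stays open for 5 weeks (0.00913, 0.00233 to 0.0173), 9 weeks (0.00423, 0.00108 to 0.00766) and 11 weeks (0.00612, 0.00321 to 0.00929), whose intervals overlap that of replicates 1 to 4. The intervals resample genes and not arrays or birds, so the comparison with 7 weeks holds for these arrays only. Smaller differences between the lines at the early ages stay open as a hypothesis. The covariance over all arrays was 0.00056 (1.99e-05 to 0.00113) at 1 week, below the intervals at 5, 7 and 11 weeks and overlapping that at 9 weeks. It cannot decide, since differences between birds or arrays enter it and weigh less over 12 arrays than over 4. At 1 week it was 0.00221 on 4 arrays and 0.000286 on the 8 of replicates 5 to 12. Compression of replicates 1 to 4 by the authors' normalization was not tested. At 1 week 1 probe was called, 2 of 100 splits gave as many, and the highest other gave 1. These splits treat the arrays as independent, while birds were reused, and differences between birds follow the real orientation but not the other splits, so chance was not excluded. At 3 weeks limma called 0, with 27 at an unadjusted p under 0.05, all 100 splits gave as many, the highest other gave 0, and chance was not excluded.

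The third pattern was that the acute phase and chaperone lists shifted to the ORM1 side at 7 weeks and 4 of 8 metabolic lists to the TTR side (camera). Cholesterol synthesis (adjusted p = 0.897), fatty acid oxidation (0.451), glycolysis (0.779) and gluconeogenesis (0.469) did not pass, of the 4 lists xenobiotic metabolism alone passed with an estimated correlation (adjusted p = 0.0432), and the enzymes VNN2 (2.02), HSD11B1B (1.42) and EHHADH (0.83) were called on the ORM1 side. A single array stays open as a cause of the calls. The acute phase and chaperone lists kept the ORM1 side without each array in turn. Their highest unadjusted p (camera) was 0.0227 without replicate 1 and 0.0394 without replicate 3. These p-values were not adjusted over lists and ages, as the calls were, so they do not decide. For the metabolic lists the highest unadjusted p was 0.136 without replicate 2. Another share of hepatocytes was not settled either. Both groups are made by hepatocytes, and 30 plasma protein genes minus 65 metabolic genes gave 0.50 on average (0.495, SD 0.129, above 0 on 4 of 4 arrays, from 0.304 to 0.576). The 65 genes were those of the 4 shifted lists, and the plasma genes included the shifted acute phase list, so this difference restates the pattern. With lipoproteins added and all 8 metabolic lists, called or not, the difference was 0.33 (42 and 114 genes, SD 0.143, 0.157 to 0.504). The shifted lists were still among these genes. On 2 of the 4 arrays the means of both narrower groups had the same sign, so a different share stays open. Leukocytes stay open, with an unadjusted p of 0.168 for their markers on the ORM1 side, as does blood, with HBBA at 0.86. A difference in the hepatic acute phase response between the lines may underlie the pattern and was not tested further.

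Other splits of 4 arrays number 3 with the real one, too few for a share under 0.05. The real and the highest other counts were 50 and 3 at 5 weeks, 187 and 1383 at 7 weeks, 54 and 0 at 9 weeks and 25 and 0 at 11 weeks (limma, with 569, 750, 732 and 268 probes at an unadjusted p under 0.05 in the real split), so that 1 of 3 splits gave as many at 5, 9 and 11 weeks and 2 of 3 at 7 weeks. The 1383 came from replicates 1 and 4 against 2 and 3 at 7 weeks, which points to a structure of these arrays apart from the lines, and 2 probes of a gene correlated in it by -0.0327, against 0.271 in the real split. At 9 weeks that correlation was lower in the real split (0.109) than in the others (0.206 and 0.251), while it was higher at 5 weeks (0.237 against 0.208 and 0.113) and at 11 weeks (0.32 against 0.19 and 0.209). For the mean over the ages the 277 called were matched by 1 of 100 splits, the real one, and the highest other gave 252. With the arrays of 5 to 11 weeks alone split it was 1 of 81, and the highest other gave 211. Chance can be excluded at the level of 1 in 20 for a part of the ratio that follows the orientation. At every age the orientation also followed odd and even replicate numbers, so a structure tied to these numbers is not told apart. The 277 are differences between the lines only if the ratios had not been turned when deposited.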

How the results depend on the processing

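The readings of the ratios as already turned, a dye effect per age or per age and replicate set, the fits without the 3 arrays that ran against their orientation, the ways to count the near-identical pair, and the list tests repeated with centred or scaled arrays or without an array were chosen after the data were seen; the other alternatives were planned. Counts are of probes past an adjusted p of 0.05 by limma, for 1, 3, 5, 7, 9 and 11 weeks, then the mean, late minus early and the F test over ages. They were 1, 0, 50, 187, 54, 25, 277, 74 and 99, and those within 1.5 times are left out below. The cause of a change was not tested unless stated.

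Scaling all arrays to the same MAD gave 10, 1, 2 and 15 at 1 to 7 weeks, 175 for the mean, 10 for late minus early and 24 by the F test, with 66.7% on the TTR side at 7 weeks against 55.1%. Array weights gave 29, 6, 90, 8, 947 and 15, then 117 and 296 for late minus early and the F test. They put 5 weeks at 77 and 13 and 9 weeks at 568 and 379 on the sides of ORM1 and TTR, with a weight of 0.0765 for replicate 4 at 5 weeks, 0.113 for replicate 2 at 7 weeks and 5.99 for replicate 5 at 3 weeks. A separate fit per age gave 4, 1, 0, 25, 2 and 5 (with fewer arrays to estimate the spread). Probes valued on all arrays (4139, so fewer were tested) gave 0 at 1 week, 31, 111, 21 and 8 at 5 to 11 weeks, then 159, 37 and 56. Without a dye effect 32 passed at 5 weeks, 21 and 11 on the sides of ORM1 and TTR, and 49 for late minus early. With fewer arrays at 1 and 3 weeks (replicates 1 to 4) the counts were 0 at 1 week, 9, 53, 9 and 3 at 5 to 11 weeks, 27, 0 and 0. Replicates 5 to 8 gave 0 at 1 week, 13, 80, 20 and 5, then 62, 0 and 7, and replicates 9 to 12 gave 0, 14, 78, 20 and 7, then 83, 0 and 7.

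Ratios read as already turned gave 1250, 626, 3088, 2272, 594, 1034, 3020, 1281 and 3319. The part that the main model fits as a dye effect then counts as a line effect by construction. A dye effect per age gave 2 at 1 week, 110, 376, 226 and 50 at 5 to 11 weeks, then 502, 130 and 207, and per age and replicate set 2, 157, 435, 329 and 57, then 562, 153 and 267. That setting put 194 and 135 of the 329 at 9 weeks on the sides of ORM1 and TTR. Without the 3 arrays 5 weeks had 950 (615 and 335), the mean 677, late minus early 168 and the F test 241, and with a dye effect per age and set besides, 2 at 1 week, 1450, 633, 525 and 107, then 1607 (975 and 632, against 84 and 193), 445 and 903. These arrays were picked because they ran against the line effect of the others. Their removal raises the agreement between arrays by construction, so the higher counts do not favour this setting.

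Leaving out each array in turn gave 1 to 1, 0 to 0, 14 to 946, 133 to 370, 23 to 77, 11 to 19, 216 to 633, 52 to 198 and 80 to 266. The 946, 633, 198 and 266 came without replicate 4 at 5 weeks, and the 370 without replicate 1 at 7 weeks. Median centring (1, 0, 47, 182, 51, 22, 276, 71 and 86), the replicate number as a block (1, 0, 50, 187, 53, 25, 255, 70 and 102, consensus correlation -0.0358), no probe filter, probes averaged per gene, the trend and robust options and the near-identical pair counted as 2 arrays or as 1 stayed within 1.5 times for each count. Of 38 arrays 10 matched best with their own replicate number at another age. Residuals of the same number correlated with a median of 0.179 and a lowest of -0.355 (58 pairs), against a median of -0.00222 for other pairs (510). Some structure shared by the arrays of a number is thus not excluded.

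Single genes were not compared under the reading as already turned, where a sign has another meaning. Of 3132 values of named genes past the threshold under the other settings, 2691 stayed past it in the same direction, 441 kept the direction only and 0 turned, while 43 of 1843 values of genes not called passed. With scaled arrays 44 of 94 no longer passed, with array weights 42 of 94 and in separate fits 51 of 66. The uncalled second probe of FASN turned from 0.14 to -0.75 at 7 weeks and from 0.027 to -0.44 for the mean when probes were averaged per gene, by construction, as it was averaged with the called probe. Of 150 list tests 13 passed, 5 with an estimated correlation, 1 by fry and 8 with scaled arrays. Calls for small differences rest on 4 arrays at 5 to 11 weeks, and signal over background was not analysed here.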

Other observations

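The second probes and the look at single genes here were chosen after their values were seen.

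Both fatty acid binding proteins of liver were measured. LBFABP, the basic form, had -2.02 at 7 weeks (log2, SE 0.25, 4.04-fold, adjusted p = 1.1e-06, limma, 4 of 4 arrays) and -0.58 over all ages, on the TTR side, whereas FABP1 had 0.76, 0.86, 0.081 and 0.94 at 5, 7, 9 and 11 weeks, past the threshold at none of them (adjusted p = 0.0675 at 7 weeks) but past it for late minus early (0.73, SE 0.17, adjusted p = 0.0208). Which line is the higher depends on the unstated direction of the ratio. Whether the pair differ from each other was not tested.

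TF, transferrin, had 0.082 and 0.11 at 1 and 3 weeks, 0.32 at 5 weeks, 0.93 at 7 weeks, -0.12 at 9 weeks and 0.47 at 11 weeks, with 0.31 for late minus early (SE 0.069, adjusted p = 0.0141 as a gene). CP, ceruloplasmin, had 0.45 at 5 weeks, 1.54 at 7 weeks, -0.15 at 9 weeks and 0.30 at 11 weeks, with 0.52 for late minus early (SE 0.13, adjusted p = 0.037). ORM1 had 1.08 at 5 weeks (adjusted p = 0.0972 as a probe), -0.016 at 9 weeks and 1.00 at 11 weeks (adjusted p = 0.28 as a probe). It was past the threshold only at 7 weeks (limma, 12, 10, 4, 4, 4 and 4 arrays).

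Probes of 1 gene did not always move together. EZH2 had -2.22 and -0.04 at 7 weeks, ATP6V1A -1.60 and 0.07, and FASN -1.65 and 0.14. The first of these ATP6V1A probes had -1.06, -1.60, -0.057 and -0.40 at 5, 7, 9 and 11 weeks. That lay close to a probe of TTR, with -1.25, -1.63, 0.016 and -0.38. Whether these probes measure separate transcripts was not tested. Over 580 genes with 2 probes, the line effects of both correlated with r = 0.124 at 1 week, 0.209 at 3 weeks, 0.237 at 5 weeks, 0.271 at 7 weeks, 0.109 at 9 weeks and 0.32 at 11 weeks. In shuffled pairs the upper bound of a 95% range lay between 0.0785 and 0.0894. The median absolute deviation of the log2 ratio differed between the hybridisation sets, with medians of 0.248 for replicates 1 to 4 and 0.159 for replicates 5 to 12 at 1 week, 0.307 and 0.14 at 3 weeks, and 0.392, 0.38, 0.232 and 0.244 at 5, 7, 9 and 11 weeks.

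The replicates 3 and 4 at 3 weeks that were left out gave nearly the same value at 9493 spots (r = 0.9999) under opposite dye labels. Counted as 1 array with either orientation, or kept as 2, they moved no count of probes by more than 1.5 times.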
